A study of Mus musculus with 92 samples.

How the data were processed

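The series holds 92 samples, of which the 39 with RNA-Seq, TAB-Seq or methylC-Seq tables were used: 18 RNA-Seq, 9 TAB-Seq and 12 methylC-Seq samples. The other 53, which include ChIP-Seq of histone marks, were not analysed here. Samples were grouped by genotype (wild type, Tet1-/-, Tet2-/-) and stage (ES cells, day 3, day 6) from their titles, and replicate numbers come from the same titles. Technical replicates of one biological replicate were summed, so every group had n = 2.

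Per the labels' protocols, RNA was extracted with Trizol from 2 M cells (M, units of 1,000,000), poly(A)-selected and made into strand-specific libraries by the dUTP method with 7 to 10 PCR cycles. DNA was sheared to about 300 bp, a spike-in of 0.5% was added, and bisulfite conversion was followed by 8 to 11 PCR cycles. TopHat, Bowtie, Picard and the mm9 build are named, per the submitters' processing notes. Versions and settings of these tools are not given in the sources used here. PCR duplicates without molecular identifiers are not independent molecules, so the intervals and floors given cover counting error only.

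The deposited RNA tables list 23,327 gene models with exon and intron counts on the sense and antisense strands and the RPKM of each. Exon sense counts, whole numbers as the authors deposited them, entered every main test. The RPKM values printed are those the authors deposited, scaled by the authors to gene length and library size, with 0.05 added, since genes with a count of 0 are listed at 0.05. Exon counts were taken on the annotated strand, so antisense partners are kept apart, but reads of near-identical copies or of overlapping genes on one strand, such as Rnase4 and Ang, may be shared. In 103 entries the symbol repeats that of an earlier entry. These were kept as separate gene models and were tested where their mean RPKM was at least 1. Intron counts made up 21.2 to 28.1% of sense counts and antisense counts 1.46 to 2.26% of exon counts. Exon counts per library were, in M and by replicate, 20.5 and 35.7 in wild-type ES cells, 21.2 and 40.0 in Tet1-/- ES cells, 31.9 and 39.3 in Tet2-/- ES cells, 37.2 and 32.7 in wild type at day 3, 33.1 and 37.2 in Tet1-/- at day 3, 40.8 and 31.7 in Tet2-/- at day 3, 31.0 and 27.4 in wild type at day 6, 31.5 and 34.5 in Tet1-/- at day 6, and 36.3 and 32.1 in Tet2-/- at day 6. The 10 most abundant genes took 10.2 to 21.3% of a library.

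The deposited methylC-Seq and TAB-Seq tables give for each CpG the modified reads, all reads and their percent, with the percent computed by the authors from those counts. Both strands of a CpG share an entry, and whether positions count from 0 or 1 is not given in the sources used here, which moves a CpG by at most 1 base against its 1 kb window. The tables cover 19,687,543 CpG positions in at least 1 library. Reads at CpG per biological replicate were, in M, 161 to 330 for methylC-Seq of ES cells, 197 to 569 for TAB-Seq and 61.8 to 75.6 for methylC-Seq at day 3. Neither conversion rates nor the protection of 5hmC in TAB-Seq were corrected for, so all levels are as called. No mm9 genome or annotation was used, and gene positions come from the deposited RNA tables.

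Expression was tested with edgeR 4.0.16 (R 4.3.3) by TMM scaling and the quasi-likelihood F test on the exon counts of all 18 libraries, with 1 coefficient for each of the 9 groups, two-sided, with Benjamini-Hochberg adjustment at 0.05. The 11,882 genes with a mean RPKM of at least 1 over the 18 libraries were tested. The biological coefficient of variation was 0.121, with 9 residual degrees of freedom and a prior of 3.97. The design written beforehand named limma on log2(RPKM + 1), with edgeR in its place if the tables held counts, and they did. On simulated counts the test recovered 82 to 89% of 100 genes changed 2-fold and 95 to 100% of 100 changed 4-fold, and false calls made up 2.70 to 7.73% of calls, depending on the comparison. A fold against a group with no counts is a lower bound against a floor of 3 counts over the group, and a ratio to 1 to 3 counts is given with its exact 95% interval.

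Gene lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over lists within a comparison, and again with an estimated correlation. The 17 lists were naive pluripotency, formative and primed epiblast, neural progenitor, neuronal, Hox genes, retinoic acid responders, primitive endoderm, mesendoderm, trophoblast, germline, two-cell-like, imprinted, DNA modification machinery, Nodal and Lefty signalling, Wnt targets, fibroblast (feeder cells) and housekeeping. Fold changes were computed against shared wild-type libraries, so 10 simulations of unchanged groups against them were set beside the observed correlation and covariance.

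The rule for named genes was fixed with the design. It takes Tet1, Tet2 and Tet3 in every group; for each genotype comparison the 12 largest changes each way among genes past the threshold with both knockout libraries on the same side of both wild-type libraries, leaving out predicted, Rik, LOC, microRNA, snoRNA and ribosomal pseudogene symbols; and up to 4 members of each list past the threshold, or else up to 2 as values. Stage comparisons and interactions take 6 each way, the latter without the rule on sides, and windows take 5 each way within 10 kb of a gene with a symbol. Of the genes that met the rule the text prints only a part, picked after their values were seen, and some results are not reported here.

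Windows of 1000 bp with at least 4 CpG and at least 20 reads in every biological replicate were tested with a quasi-binomial model per window on the read counts, its dispersion moderated across windows with limma's squeezeVar, and Benjamini-Hochberg adjustment. The median prior reached the cap of 1,000,000 degrees of freedom, against 3 residual ones in ES cells and 2 at day 3, so a typical window's own spread had almost no weight and its p-value rests on the dispersion of windows with like reads. A window was called at adjusted p under 0.05 and a difference of at least 10 percentage points for methylC-Seq or 5 for TAB-Seq. Median reads per window and replicate were 118 for methylC-Seq of ES cells, 127 for TAB-Seq and 44 for day 3. The 3 genotypes of ES cells shared a fit, and day 3 had its own. The moderation of the dispersion was changed after the data had been tested once. The version first run recovered 0% of changed windows in some simulated designs with a replicate left out, because groups with no modified reads, or only modified ones, counted as fully informative. A version that counts only informative groups, with robust moderation and the expected modified reads as covariate, was chosen on simulated reads alone, as the one with the best recovery among those with false calls at or under 6% in every simulated design. It recovered 52.8% of 20-point and 98.6% of 40-point changes in methylC-Seq of ES cells, 85.7% of 10-point and 99.3% of 20-point changes in TAB-Seq, and 49.5% and 97.1% of 20-point and 40-point changes at day 3, among 6,000 changed of 60,000 simulated windows. False calls were 5.53%, 2.10% and 3.93%. The simulated libraries held no shift common to a whole library, whereas the wild-type methylC-Seq replicates of ES cells stood 9.04 points apart. All windows of a simulated design were also drawn with the same dispersion parameter, so windows with a dispersion of their own were not simulated. These rates therefore do not cover calls that arise from such shifts or from such windows, and the choice of moderation was not tried on them.

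Global levels are modified reads over all reads at CpG, compared by exact permutation tests, which cannot go below 0.333 with 2 against 2. Classes by wild-type level were set from wild-type replicate 1 and measured in the other replicates. Promoters are 500 bp on each side of a gene's start and count as dense with at least 20 CpG. Genes near windows had a window within 10 kb.

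Alternatives fixed beforehand were 0.1 in place of 1 added to the RPKM, no filter on low values, quantile normalization, the replicate number as a block, each library left out in turn, only the groups compared in the fit, other minimums of reads (10 and 50), windows of 500 bp, technical replicate 1 alone, autosomes alone, positions with at least 10 reads, limma on log2 ratios, classes from wild-type replicate 2, 10,000 random lists matched on expression, fry, and flanks of 0 and 50 kb. Chosen after seeing the data were DESeq2 1.42.0, edgeR with RLE scaling, limma on log2(RPKM + 1) beside edgeR, the first moderation of the dispersion, libraries less their median, classes of wild-type 5hmC and of gene parts, overlaps of windows, further window sets near genes, lists from Tet2-/-, chromosome medians, and cardiac genes without 1 library. Tables were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and arrow 21.0.0. Exact permutation tests of global levels were run with Python and numpy, and plots were drawn with matplotlib 3.10.9.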

Results

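Cytosine modification and gene expression were measured in mouse embryonic stem (ES) cells of 3 genotypes: wild type, Tet1-/- and Tet2-/-. Tet1 and Tet2 encode dioxygenases that oxidise 5-methylcytosine (5mC) to 5-hydroxymethylcytosine (5hmC). MethylC-Seq, which sequences bisulfite-converted DNA, reads 5mC and 5hmC together. TAB-Seq, in which 5mC is oxidised enzymatically before conversion, reads 5hmC alone. Both assays covered ES cells of the 3 genotypes with 2 biological replicates each, and methylC-Seq also covered wild-type and Tet2-/- cells at day 3 of differentiation towards neural progenitor cells, again with 2 replicates each. RNA-Seq covered ES cells, day 3 and day 6 in all 3 genotypes with 2 replicates per group, which made 18 libraries. The RNA libraries held 20.5 M to 40.8 M exon counts (M, counts in units of 1,000,000). Mean reads per CpG position over the biological replicates ranged from 9.09 to 20.2 for methylC-Seq of ES cells, from 11.1 to 30.2 for TAB-Seq and from 4.71 to 5.25 for methylC-Seq at day 3. Histone-mark libraries and other samples of the series were not analysed here. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

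The targeted genes were examined first. Tet1 RNA stood at 25.5 and 22.7 RPKM in the replicates of Tet1-/- ES cells, against 42.5 and 44.7 RPKM in wild type and 39.2 and 48.3 RPKM in Tet2-/- ES cells. This difference between Tet1-/- and wild type passed the test (log2 fold change −0.90 ± 0.12 (SE), edgeR adjusted p = 2.6e-04, n = 2). At day 3 Tet1 was at 14.2 and 15.0 RPKM in Tet1-/- and at 20.0 and 20.3 RPKM in wild type (adjusted p = 0.020). That call was lost without any single library, with adjusted p = 0.086 and 0.091 without wild-type replicates 1 and 2 and 0.18 and 0.079 without Tet1-/- replicates 1 and 2. By day 6 Tet1 lay at 5.12 and 5.07 RPKM in Tet1-/- and 5.73 and 6.10 RPKM in wild type, with adjusted p = 0.58. Tet2 RNA was at 21.9 and 20.6 RPKM in Tet2-/- ES cells and 28.4 and 28.8 RPKM in wild type (adjusted p = 0.11), and at 1.35 and 1.76 RPKM against 2.88 and 2.18 RPKM at day 3 (adjusted p = 0.089). Only at day 6 did the Tet2 difference pass, with 1.81 and 1.87 RPKM in Tet2-/- against 4.38 and 4.57 RPKM in wild type (log2 fold change −1.24 ± 0.20, adjusted p = 0.0022). Counts were summed over all exons of each gene, so the deletions themselves are not resolved. Reads from outside the deleted parts may remain, and whether they make up the remaining RNA was not tested. Tet3 was at 1.06 ± 0.0995 RPKM in Tet1-/- ES cells and 0.735 ± 0.0429 RPKM in wild type (adjusted p = 0.020), a call lost without wild-type replicate 2 (0.11) or Tet1-/- replicate 2 (0.19).

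How far modification over the whole genome differed between each knockout and wild type was asked first for ES cells. CpG 5hmC stood at 4.03 ± 0.84% of reads in wild type, 2.45 ± 0.06% in Tet1-/- and 1.44 ± 0.15% in Tet2-/- ES cells (SD, n = 2 each). As called, the Tet1-/- level was 60.7% and the Tet2-/- level 35.8% of wild type. Reads called modified in error were not subtracted, so the shares of 5hmC kept may be lower. Combined 5mC and 5hmC stood at 60.1 ± 6.39% in wild type, 49.2 ± 3.27% in Tet1-/- and 51.4 ± 0.77% in Tet2-/- ES cells, differences of −10.9 and −8.68 percentage points. Every knockout replicate of both assays lay below both wild-type replicates, but the exact two-sided permutation p was 0.333, the smallest that 2 against 2 allows. The wild-type methylC-Seq replicates stood 9.04 points apart. At day 3 the combined level was 84.0 ± 0.35% in wild type and 83.2 ± 0.71% in Tet2-/- cells, a difference of −0.75 points (exact permutation p = 0.667). Leaving out single libraries moved the ES difference in combined modification between −15.4 and −6.35 points for Tet1-/- and between −13.2 and −4.15 points for Tet2-/-. The smallest values, −6.35 and −4.15, came without wild-type replicate 2 and the largest without wild-type replicate 1. For 5hmC in Tet1-/-, the range was −2.18 (without wild-type replicate 2) to −0.99 points (without wild-type replicate 1), and for day 3 −1.25 (without Tet2-/- replicate 2) to −0.24 points (without Tet2-/- replicate 1).

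**Figure D1:**
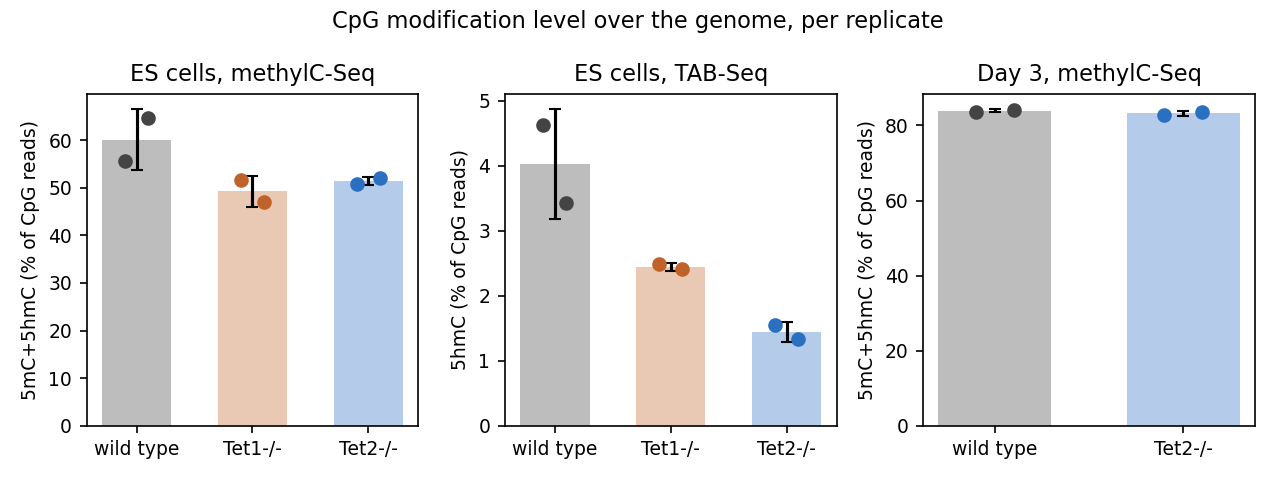
CpG modification level over the genome as the percentage of CpG reads called modified, for methylC-Seq of ES cells, TAB-Seq of ES cells and methylC-Seq at day 3. Bars show the mean of 2 biological replicates, error bars the SD and points the replicates. All knockout points lie below both wild-type points in ES cells, and at day 3 the groups lie within 2 points of each other.

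Local changes in Tet2-/- ES cells were sought in 1 kb windows of the mm9 genome. The p-values of single windows rest mainly on the spread shared by windows and hardly on their own replicates. A window inside Dpys, which encodes dihydropyrimidinase of pyrimidine breakdown, went from 0% and 0% in the wild-type replicates to 61.8% and 69.4% in Tet2-/- (chromosome 15, 39,683,001 to 39,684,000; 4 CpG; 323 reads; adjusted p = 3.8e-16). A window inside Ovol2, which encodes a zinc-finger transcription factor, stood at 3.48% and 6.62% in wild type, 2.04% and 2.07% in Tet1-/- and 63.0% and 69.9% in Tet2-/- (chromosome 2, 144,134,001 to 144,135,000; 11 CpG; adjusted p = 1.2e-34). In the other direction, a window inside Gng12, which encodes a G protein gamma subunit, fell from 91.1% and 100% to 1.11% and 6.67% in Tet2-/-, with 95.7% and 84.1% in Tet1-/- (chromosome 6, 66,958,001 to 66,959,000; 11 CpG; adjusted p = 8.7e-24). Of 1,649,009 windows tested, 32,928 (2.00%) were raised and 308,607 (18.7%) lowered by at least 10 points, and the median difference over all windows was −12.3 points. The raised windows averaged 18.4% and 25.7% in the wild-type replicates, 21.2% and 20.7% in Tet1-/- and 40.9% and 41.2% in Tet2-/-. Their 5hmC was 5.88% and 5.57% in wild type, 4.08% and 3.83% in Tet1-/- and 2.16% and 2.09% in Tet2-/-. Of the raised windows also tested by TAB-Seq, 27.4% lost 5hmC in Tet2-/- (8,980 of 32,801, against 4,676 for independent lists), whereas 3.25% of the lowered windows did (9,838, against 43,096). A loss call needs a fall of at least 5 points, so a window with little 5hmC in wild type cannot get one. Over the genome the Tet2-/- 5hmC level as called was 35.8% of that of wild type. Whether this share differed between raised and lowered windows was not tested. The numbers of raised and lowered windows turned once library-wide levels were removed: with each library less its own median, limma called 56,407 raised and 15,904 lowered. The count of 341,535 became 679,381 without wild-type replicate 1, 104,664 without wild-type replicate 2, 25,877 without Tet2-/- replicate 2 and 6,096 without Tet2-/- replicate 1, of which 4,313 were raised and 1,783 lowered.

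Fewer windows were raised in Tet1-/- ES cells. A window inside Akr1d1, which encodes a steroid reductase, stood at 1.25% and 4.07% in wild type, 79.4% and 59.7% in Tet1-/- and 42.0% and 33.0% in Tet2-/- (chromosome 6, 37,501,001 to 37,502,000; 14 CpG; 1309 reads; adjusted p = 1.4e-34). A window inside Zdhhc14, a palmitoyltransferase gene, rose from 3.00% and 3.52% to 69.4% and 60.9%, with 62.0% and 65.6% in Tet2-/- (chromosome 17, 5,660,001 to 5,661,000; 10 CpG; adjusted p = 6.1e-33). A window inside Nod1, which encodes an intracellular sensor of bacterial peptidoglycan, fell from 89.1% and 96.6% to 0% and 2.26% in Tet1-/-, with 82.3% and 88.9% in Tet2-/- (chromosome 6, 54,904,001 to 54,905,000; 10 CpG; 482 reads; adjusted p = 2.7e-27). Over the same windows tested, 2,927 (0.178%) were raised and 225,804 (13.7%) lowered. Of the raised windows, 1,818 were also raised in Tet2-/- against 58.4 for independent lists, and 104,935 lowered windows were shared against 42,258. Both comparisons use the same wild-type libraries, so part of these excesses may come from shared controls. The count of 228,731 became 661,890 without wild-type replicate 1, 32,206 without wild-type replicate 2 and 13,273 without Tet1-/- replicate 2. With each library less its median, limma called 3,041 raised and 2,402 lowered.

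Windows with less 5hmC than in wild type were sought with TAB-Seq. A window inside Cnot2, which encodes a subunit of the CCR4-NOT deadenylase, held 31.8% and 13.2% 5hmC in wild type and 0% and 1.18% in Tet2-/- (chromosome 10, 115,975,001 to 115,976,000; 5 CpG; 453 reads; adjusted p = 2.5e-07). A window inside Chn2, which encodes a Rac GTPase-activating protein, held 23.5% and 9.33% in wild type, 0.926% and 6.15% in Tet1-/- and 0% and 0% in Tet2-/- (chromosome 6, 54,143,001 to 54,144,000; 13 CpG; 625 reads; adjusted p = 2.5e-06). Of 1,747,173 windows, 237,498 (13.6%) lost at least 5 points of 5hmC in Tet2-/- and 114 gained them. The test called 7,542 windows lowered and 17 raised in Tet1-/-, and 6,579 of the lowered windows (87.2%) were also lowered in Tet2-/- against 1,025 for independent lists, with the wild-type libraries shared. In Tet1-/-, a window inside Trit1, a tRNA modification gene, held 22.4% and 26.6% in wild type and 2.20% and 2.60% in Tet1-/- (chromosome 4, 122,703,001 to 122,704,000; 16 CpG; 1610 reads; adjusted p = 1.5e-04). That call was lost without Tet1-/- replicate 1 (0.18) or replicate 2 (0.55). The Tet1-/- count of 7,559 was not stable: it was 6 without Tet1-/- replicate 1, 1 without Tet1-/- replicate 2, 105 without wild-type replicate 1 and 44,672 without wild-type replicate 2. limma on log2 ratios called 0 windows there, while 305,398 had an unadjusted p under 0.05 in the quasi-binomial test. The Tet2-/- count of 237,612 was 109,354 without wild-type replicate 1 and 141,123 without Tet2-/- replicate 1, and limma called 163,918. Less each library's median, limma called 0 windows in either knockout, against 768,386 with an unadjusted p under 0.05 in Tet2-/- by the quasi-binomial test, and the Cnot2 and Chn2 calls were then lost.

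CpG density separated these losses in percentage points, a scale on which a class with a low wild-type level has little to lose. In windows with 4 to 9 CpG, combined modification was 67.1 ± 5.32% in wild type and 53.4 ± 0.29% in Tet2-/- ES cells, a difference of −13.7 points, and the difference was −8.36 points in windows with 10 to 19 CpG. In windows with 20 to 39 CpG it was −3.64 points and in those with 40 or more 0.49 points, both with the replicates of the groups overlapping. The same 4 classes in Tet1-/- gave −12.7, −10.1, −7.06 and −0.45 points. Promoters with at least 20 CpG stood at 6.12 ± 1.41% in wild type, 5.2 ± 0.15% in Tet1-/- and 7.06 ± 0.83% in Tet2-/-, while gene bodies stood at 62.7%, 52.1% and 54.3%. Their 5hmC was 1.24% in wild type, 0.912% in Tet1-/- and 0.666% in Tet2-/- at such promoters, and 4.58%, 2.79% and 1.55% in gene bodies. Windows that wild-type replicate 1 put at 80% or more were 16.7 points lower in Tet2-/- (a difference of −16.7) and differed by −11.8 points in Tet1-/-. Those under 10% differed by 1.92 points in Tet2-/-, where both knockout replicates lay above the wild-type replicate held out from the classing. Wild type is here replicate 2 alone, which stood 9.04 points above replicate 1 over the genome. Classed on replicate 2 and measured against replicate 1, the windows at 80% or more differed by −10.1 points in Tet2-/- and −7.27 points in Tet1-/-, and those under 10% by 2.30 points in Tet2-/-. No class can reach a permutation p under 0.333, and the division by promoter and gene body was added after the data were examined.

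At day 3 the question was whether the ES changes of Tet2-/- cells persisted. A window inside Sh3bp4, which encodes a regulator of receptor endocytosis, stood at 18.6% and 0% in wild type and 78.4% and 80.6% in Tet2-/- cells (chromosome 1, 90,992,001 to 90,993,000; 16 CpG; 220 reads; adjusted p = 3.3e-14). A CpG-dense window inside Grb10, an imprinted gene for an adaptor that restrains insulin signalling, fell from 50.8% and 77.3% to 6.56% and 8.29% (chromosome 11, 11,926,001 to 11,927,000; 101 CpG; 941 reads; adjusted p = 2.8e-53). A window inside Zfp777, a zinc-finger gene, fell from 58.8% and 78.4% to 5.24% and 7.43% (chromosome 6, 47,974,001 to 47,975,000; 49 CpG; 612 reads; adjusted p = 2.1e-40). Of 834,274 windows, 852 were raised and 1,337 lowered, and 62,723 had an unadjusted p under 0.05. Of 22,765 ES-raised windows tested at day 3, 282 (1.24%) were raised again against 23.4 for independent lists, and of 133,006 ES-lowered windows 556 (0.418%) were lowered again against 216. The ES-raised windows had a median day 3 difference of 3.16 points against 0.12 points over all windows. These windows stood at 77.6% and 78.1% in wild type and at 81.2% and 82.4% in Tet2-/- cells at day 3. The day 3 count of 2,189 was 1,216 and 1,131 without wild-type replicates 1 and 2, 1,001 and 1,299 without Tet2-/- replicates 1 and 2, and limma on log2 ratios called 1 window, with the Sh3bp4 call lost (0.43) and the Grb10 call lost (0.45).

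**Figure D2:**
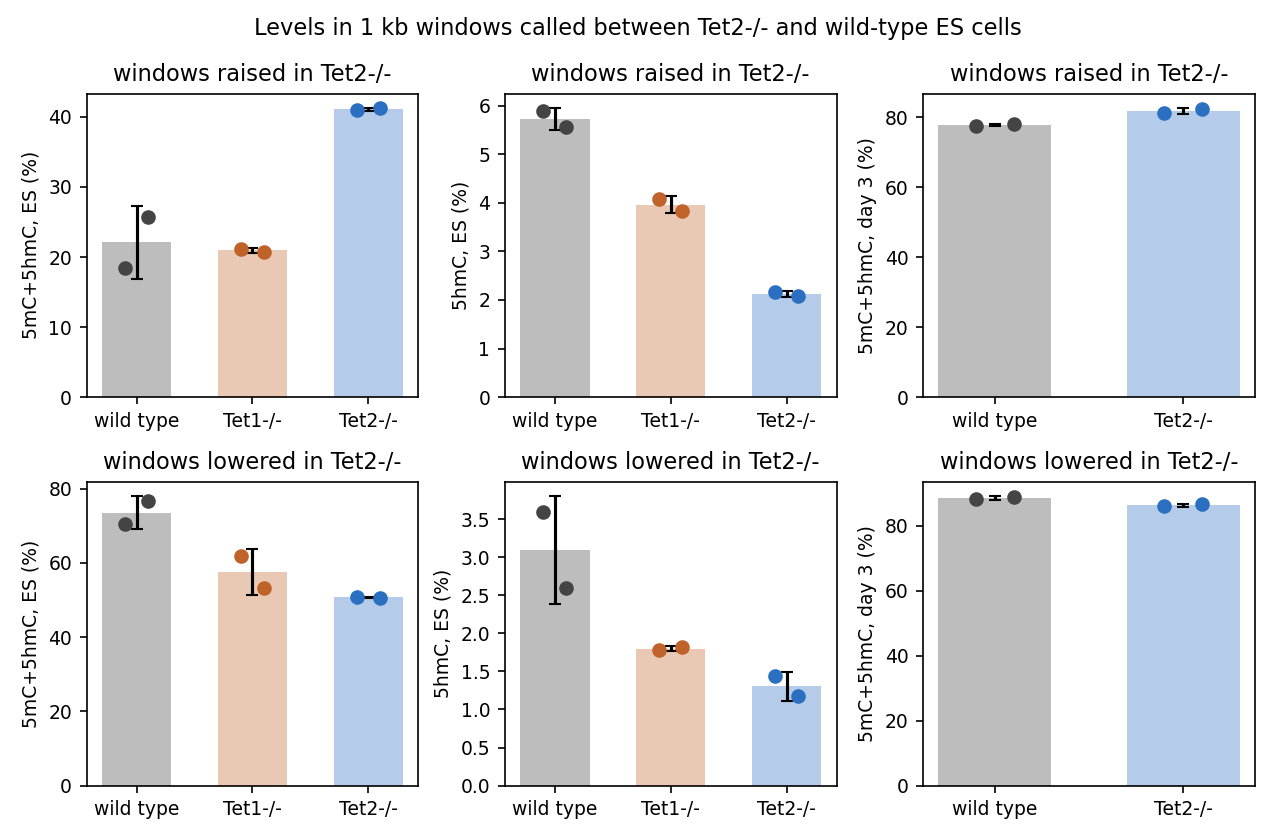
Mean modification in the 1 kb windows raised (top) and lowered (bottom) in Tet2-/- ES cells, as the percentage of CpG reads called modified, by methylC-Seq in ES cells, TAB-Seq in ES cells and methylC-Seq at day 3. Bars show the mean of 2 biological replicates, error bars the SD and points the replicates. Wild type went from 18.4% and 25.7% in ES cells to 77.6% and 78.1% at day 3 in the raised windows, which were picked for their difference in ES cells.

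Wild-type differentiation set the background for the expression comparisons. At day 3 naive pluripotency genes were lower and epiblast genes higher than in ES cells. Klf4, a naive pluripotency factor, fell from 109 ± 15.6 to 0.585 ± 0.0354 RPKM (log2 fold change −7.89 ± 0.41, edgeR adjusted p = 6.4e-09, n = 2), and Zfp42, the ES-cell marker Rex1, fell from 111 ± 6.17 to 5.63 ± 1.11 RPKM (adjusted p = 1.4e-09). Of 24 naive pluripotency genes, 21 fell and 1 rose (list adjusted p = 1.5e-14). Members are counted after adjustment over all genes, and where a called list has only that count, adjustment over the list alone gave the same. Of 14 formative and primed epiblast genes, 12 rose and none of them fell (list adjusted p = 9.2e-10), among them Fgf5, a growth factor of the post-implantation epiblast, at 28.0 ± 5.22 against 0.0915 RPKM, and the de novo methyltransferase gene Dnmt3a at 20.4 ± 1.99 against 2.72 RPKM. Both list calls held with an estimated correlation (adjusted p = 0.011 for each), while that of 28 imprinted genes (12 higher, 4 lower, adjusted p = 0.021) had adjusted p = 0.54 with an estimated correlation. Tet2 fell from 28.6 ± 0.263 to 2.53 ± 0.492 RPKM (log2 fold change −3.75 ± 0.21) and Tet3 rose to 3.40 RPKM. In all, 3,576 genes rose and 3,577 fell among 11,882 tested. On the scale of log2(RPKM + 1), limma gave 5,121 higher and 2,411 lower, and quantile normalization gave 4,099 and 3,258.

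Single genes had risen far by day 6. Hoxb5, a hindbrain and cervical patterning gene, was at 19.8 RPKM with no counts in ES cells, at least 914-fold higher, and Wnt1, the midbrain organiser signal, was at least 427-fold higher (floors of 3 counts over the ES group). Msx1, of the dorsal neural tube, rose from 0.160 to 27.9 ± 4.71 RPKM (log2 fold change 7.81 ± 0.34, adjusted p = 7.3e-10), and the retinoic acid receptor gene Rarb rose from 0.0959 to 11.6 ± 1.15 RPKM. Pou5f1, the core pluripotency factor Oct4, fell from 244 ± 5.24 to 12 ± 2.32 RPKM (log2 fold change −4.60 ± 0.15, adjusted p = 1.0e-10), and Tet1 fell from 43.6 to 5.92 RPKM while Tet3 rose from 0.735 to 8.76 RPKM. In total 4,138 genes rose and 4,016 fell, or 5,545 and 2,788 by limma on log2(RPKM + 1). All 17 gene lists, which were fixed together with the tests and the rule for named genes before the data were examined, are given for this comparison as members higher and lower over all genes. Naive pluripotency (0 and 23 of 24) fell with list adjusted p = 1.6e-19, the only call that held with an estimated correlation (0.0075). Rises were called for neural progenitor (20 and 1 of 22; 21 and 1 adjusted over the list alone), Hox (18 and 0 of 18), retinoic acid responder (8 and 1 of 10), primitive endoderm (10 and 2 of 14; 11 and 2 adjusted over the list alone), formative and primed epiblast (9 and 2 of 14), imprinted (18 and 4 of 28) and fibroblast genes (10 and 2 of 12). Their adjusted p values of 9.6e-08, 5.6e-06, 0.0023, 0.017, 0.018, 1.8e-05 and 7.4e-05 became adjusted p = 0.20, 0.30, 0.19, 0.49, 0.26, 0.15 and 0.12 with an estimated correlation. No call was made for neuronal (8 and 1 of 13), mesendoderm (4 and 1 of 7), trophoblast (9 and 3 of 13; 9 and 4 adjusted over the list alone), germline (0 and 3 of 5), two-cell-like (0 and 1 of 1), DNA modification (8 and 12 of 25), Nodal and Lefty (3 and 6 of 9), Wnt target (5 and 2 of 9) or housekeeping genes (3 and 3 of 10, with median and test of opposite sign).

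Expression in Tet1-/- ES cells was then compared with wild type. Nod1 rose from 0.207 ± 0.0299 to 14.6 ± 3.14 RPKM (log2 fold change 6.51 ± 0.33, edgeR adjusted p = 1.1e-07, n = 2). Ly6a, which encodes the surface antigen Sca-1, rose from 0.184 to 10.0 ± 1.33 RPKM, and the neurofilament gene Nefl rose from 2.14 ± 0.384 to 12.2 ± 1.14 RPKM. The oligodendrocyte lineage factors Olig1 and Olig2 fell, Olig1 from 6.69 ± 0.264 to 0.132 ± 0.0303 RPKM (log2 fold change −6.46 ± 0.39, adjusted p = 5.3e-07) and Olig2 from 4.76 to 0.0932 RPKM. Peg3, an imprinted zinc-finger gene, fell from 13 ± 1.85 to 2.09 ± 0.215 RPKM (log2 fold change −2.70 ± 0.22, adjusted p = 7.6e-06). Within the naive list Zfp42 rose from 111 ± 6.17 to 256 ± 13.1 RPKM and Dppa3, a maternal-effect germline gene, fell from 38.4 ± 17.1 to 6.02 ± 4.00 RPKM. No gene list was called: formative and primed epiblast genes gave 3 higher and 6 lower of 14 (3 and 7 adjusted over the list alone) with Zic2 at 3.03 against 10.7 RPKM, trophoblast genes 0 and 5 of 13 (list adjusted p = 0.085), and imprinted genes 1 and 6 of 28 (2 and 6 adjusted over the list alone; list adjusted p = 0.11). Neuronal genes had a median of −0.30 on the log2 scale although their test pointed up. Altogether 1,010 genes rose and 995 fell, or 1,127 and 708 by limma on log2(RPKM + 1), and the total of 2,005 became 1,169 without Tet1-/- replicate 1 and 1,202 without Tet1-/- replicate 2. Y-linked genes differed between the lines, with Ddx3y at 10.9 ± 0.913 RPKM in Tet1-/-, 0.801 RPKM in wild type and 0.0574 RPKM in Tet2-/-. All 3 Y-linked genes tested were higher in Tet1-/- and lower in Tet2-/-. Chromosome Y had 0.0032 and 0.00575 methylC-Seq reads per 1000 autosomal ones in the Tet2-/- replicates against 0.256 and 0.285 in wild type. In Tet1-/- it had 0.312 and 0.324, a small DNA difference beside that in Ddx3y RNA, whose cause was not tested. Chromosome 11 genes had a median change of −0.16 on the log2 scale, 29 higher and 152 lower, with its DNA reads at 66.2 per 1000 autosomal reads in Tet1-/- against 71.9 in wild type.

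Tet2-/- ES cells gave more calls. Their libraries also had higher shares of intron counts (27.3% and 28.1% of sense counts, against 23.6% and 25.6% in wild type) and of antisense counts (2.26% and 2.15% of exon counts, against 1.79% and 1.72%), and whether this adds to the calls was not tested. Rnase4, a secreted ribonuclease gene, rose from 1.01 ± 0.156 to 15.3 ± 0.471 RPKM (log2 fold change 4.02 ± 0.43, edgeR adjusted p = 6.0e-05, n = 2), and Grb14, an adaptor of insulin receptor signalling, rose from 0.146 to 4.23 ± 0.623 RPKM. Lefty2, a Nodal antagonist, fell from 166 ± 21.4 to 65.7 ± 0.771 RPKM (log2 fold change −1.33 ± 0.31, adjusted p = 0.0074), and Zfp42 fell from 111 ± 6.17 to 35.1 ± 1.80 RPKM (log2 fold change −1.66 ± 0.17, adjusted p = 3.3e-05). Olig2 had no counts in Tet2-/- and was at least 419-fold lower, while Olig1 fell to 0.123 ± 0.0116 RPKM. Dpys fell from 5.90 ± 1.10 to 0.437 ± 0.0356 RPKM. The imprinted genes went both ways: Grb10 fell from 10.1 ± 1.97 to 1.75 ± 0.0985 RPKM (log2 fold change −2.55 ± 0.13, adjusted p = 4.0e-07) and Peg3 rose to 29.1 ± 3.46 RPKM (log2 fold change 1.17 ± 0.21, adjusted p = 0.0015), with 6 of 28 higher and 2 lower. No list was called. Of 9 Nodal and Lefty genes, 1 was higher and 4 lower (2 and 4 adjusted over the list alone; list adjusted p = 0.33). In total 1,625 genes rose and 1,789 fell. That count of 3,414 became 1,904 without wild-type replicate 1 and 1,919 without Tet2-/- replicate 2. On chromosome 11 the median change was −0.16 on the log2 scale with 46 genes higher and 274 lower, and its DNA reads stood at 63.5 per 1000 autosomal reads, while chromosome 8 (121 higher, 61 lower) stood at 58.9 against 54.2 in wild type.

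The knockouts were also compared directly, in a contrast that leaves out the wild-type groups. The wild-type libraries still entered the fit that gave the scaling and the spread. Otx2, a transcription factor of the epiblast and anterior brain, was at 2.54 ± 0.104 RPKM in Tet2-/- and 0.280 ± 0.0426 RPKM in Tet1-/- ES cells (log2 fold change 3.52 ± 0.56, edgeR adjusted p = 8.8e-04, n = 2). Peg3 was at 29.1 ± 3.46 against 2.09 ± 0.215 RPKM (log2 fold change 3.87 ± 0.23, adjusted p = 5.6e-07). Zfp42 ran the other way, at 35.1 RPKM in Tet2-/- and 256 RPKM in Tet1-/- cells (log2 fold change −2.81), as did Nod1 at 0.193 and 14.6 RPKM. Of 11,882 genes, 1,260 were higher and 1,409 lower in Tet2-/-, or 896 and 1,447 by limma on log2(RPKM + 1). Among 28 imprinted genes 8 were higher and 2 lower (9 and 2 adjusted over the list alone), a list call with adjusted p = 0.039 that had adjusted p = 0.86 with an estimated correlation. The total of 2,669 became 1,147 without Tet1-/- replicate 1 and 1,254 without Tet2-/- replicate 2.

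The next comparison asked how Tet1-/- cells differed from wild type at day 3, when several naive transcripts were higher. Zfp42 stood at 13.4 ± 2.35 against 5.63 ± 1.11 RPKM (log2 fold change 1.23 ± 0.17, edgeR adjusted p = 8.5e-04, n = 2), and Klf5, a naive pluripotency factor, at 18.8 ± 4.88 against 8.82 ± 0.982 RPKM (log2 fold change 1.08 ± 0.16, adjusted p = 0.0011). Zfp42 had already been higher than in wild type in Tet1-/- ES cells, so its difference did not first appear at day 3. Of 24 naive genes, 5 were higher and 1 lower (8 and 1 adjusted over the list alone), with list adjusted p = 0.0053, which had adjusted p = 0.57 with an estimated correlation. Formative and primed epiblast genes (4 higher of 14, list adjusted p = 0.012) included Sall2, a zinc-finger factor, at 21.7 ± 1.75 against 11.7 ± 0.589 RPKM. Primitive endoderm genes (2 higher of 14, adjusted p = 0.013) included the basement membrane collagen gene Col4a2 at 3.56 against 1.23 RPKM, and these list calls had adjusted p = 0.57 and 0.95 with an estimated correlation. Nod1 stayed high at 6.82 ± 0.646 against 0.112 RPKM, Tlr2, a receptor of innate immunity, rose from 0.309 to 3.08 ± 0.25 RPKM, and the class I histocompatibility gene H2-T9 fell from 5.77 ± 0.933 to 0.531 ± 0.0552 RPKM. Altogether 605 genes rose and 686 fell. That total of 1,291 was 526 and 676 without wild-type replicates 1 and 2, and 298 and 487 without Tet1-/- replicates 1 and 2.

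In Tet2-/- cells at day 3 Rnase4 was at 20.2 ± 1.30 against 0.486 ± 0.125 RPKM in wild type (log2 fold change 5.58 ± 0.47, edgeR adjusted p = 1.9e-05, n = 2). Its neighbour Ang, the angiogenin gene, rose from 0.192 to 3.72 ± 0.118 RPKM. Because the spans of both genes overlap in the deposited tables, reads may be shared between them. Inpp5d, a phosphatase gene of blood cells, rose from 0.703 ± 0.164 to 5.44 ± 1.31 RPKM. Grb10 fell from 35.3 ± 3.58 to 1.98 ± 0.27 RPKM (log2 fold change −4.13 ± 0.14, adjusted p = 2.8e-09) and Heph, which encodes a copper-dependent ferroxidase, fell from 2.29 ± 0.219 to 0.261 ± 0.0482 RPKM. Olig2 was at least 304-fold lower. The test called 189 genes higher and 254 lower, and no gene list. The mesendoderm gene T, brachyury, gave 1.70 ± 0.993 against 11.1 ± 12.2 RPKM (adjusted p = 0.10). The total of 443 was 101 without wild-type replicate 2, 107 without Tet2-/- replicate 1 and 85 without Tet2-/- replicate 2, and limma on log2(RPKM + 1) gave 131 higher and 361 lower.

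Between the knockouts at day 3, Rnase4 (20.2 against 0.281 RPKM) and Peg3 (49.3 against 9.24 RPKM) were higher in Tet2-/-, whereas Grb10 (1.98 against 31.3 ± 0.883 RPKM; log2 fold change −3.94 ± 0.14, edgeR adjusted p = 4.7e-09) and Phlda1, a gene of apoptosis control (0.856 against 8.02 RPKM), were lower. Klf5 stood at 7.57 RPKM in Tet2-/- and 18.8 RPKM in Tet1-/- cells. Naive pluripotency (1 higher and 2 lower of 24; 1 and 4 adjusted over the list alone), primitive endoderm (0 and 4 of 14), trophoblast (0 and 2 of 13) and fibroblast lists (0 and 3 of 12; 0 and 5 adjusted over the list alone) were called lower with adjusted p = 0.041, 0.021, 0.038 and 0.041, and each had adjusted p = 0.82 with an estimated correlation. In all 803 genes were higher and 792 lower, or 518 and 1,128 by limma on log2(RPKM + 1). The total of 1,595 was 337 and 653 without Tet1-/- replicates 1 and 2, and 614 and 374 without Tet2-/- replicates 1 and 2.

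At day 6 several gene lists were called lower in Tet1-/- cells than in wild type. Pax6, a neural progenitor factor, fell from 8.12 ± 2.48 to 0.899 ± 0.55 RPKM (log2 fold change −3.15 ± 0.37, edgeR adjusted p = 1.3e-04, n = 2), the Notch effector Hes5 fell from 5.02 ± 1.42 to 0.482 ± 0.397 RPKM, and Olig3 of the dorsal neural tube fell from 10.4 ± 2.90 to 0.364 ± 0.342 RPKM. Of 22 neural progenitor genes 1 rose and 12 fell (1 and 15 adjusted over the list alone; list adjusted p = 2.2e-05, adjusted p = 0.31 with an estimated correlation), and of 13 neuronal genes 2 rose and 9 fell (3 and 9 adjusted over the list alone; 7.4e-04, adjusted p = 0.31 with an estimated correlation). Hox genes (0 and 9 of 18; 0 and 13 adjusted over the list alone) included Hoxb4, at 6.80 ± 2.86 against 25.5 ± 5.48 RPKM, with list adjusted p = 2.6e-05, adjusted p = 0.36 with an estimated correlation. Pou5f1 fell from 12 ± 2.32 to 2.46 ± 0.214 RPKM (log2 fold change −2.19 ± 0.15, adjusted p = 3.2e-06), and 13 of 24 naive genes fell and 1 rose (3 and 15 adjusted over the list alone; list adjusted p = 2.6e-12, which held with an estimated correlation, 0.045). Germline genes fell in 5 of 5, with Stra8, a gene of meiotic entry, at 0.199 ± 0.024 against 6.48 ± 1.62 RPKM (list adjusted p = 1.4e-07, adjusted p = 0.12 with an estimated correlation). Higher were Eomes of the mesendoderm at 2.26 ± 0.398 against 0.274 ± 0.057 RPKM (4 of 7 mesendoderm genes; list adjusted p = 0.0026), primitive endoderm (2 of 14, 4 adjusted over the list alone; 0.0077) and imprinted genes (8 higher and 3 lower of 28, 15 and 3 adjusted over the list alone; 0.003), with adjusted p = 0.31, 0.51 and 0.31 with an estimated correlation. Among single genes Myl7, an atrial myosin light chain, and Nkx2-5, a heart transcription factor, reached 190 ± 216 and 6.79 ± 5.57 RPKM against 3.58 ± 2.38 and 0.286 ± 0.122 RPKM (log2 fold changes 5.93 ± 1.02 and 4.99 ± 0.77, adjusted p = 0.0017 and 8.9e-04).

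In that comparison 978 genes rose and 1,241 fell, or 658 and 1,860 by limma on log2(RPKM + 1). Tet1-/- day 6 replicate 1 stood apart at −46.3 on the third principal component (3.72% of variance), against −23.2 for replicate 2. Its intron share was 24.9% of sense counts, against 22.4% in replicate 2 and 21.2% and 21.3% in wild type. Its 10 most abundant genes took 18.6% of the library, against 12.9% in replicate 2 and 14.1% and 16.1% in wild type. Whether this adds to the calls was not tested. Without replicate 1 the log2 fold change of Myl7 was 3.47 and 1,105 genes were called. Of the genes called with both libraries, 45.0% stayed past the threshold without replicate 1 and 74.6% without replicate 2. For the cardiac genes called this was 10 and 15 of 15 and for the neural progenitor genes called lower 8 and 12 of 12, with the spread then supplied by the other groups. The list of cardiac genes was drawn up after the values of Myl7 and Nkx2-5 were seen. The primitive endoderm call was lost without replicate 1 (list adjusted p = 0.25). The total of 2,219 was 1,026 without wild-type replicate 1 and 1,357 without wild-type replicate 2. With only the 4 libraries compared in the fit, 568 genes were called, and Myl7, Nkx2-5 and Actc1 were not among them.

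Imprinted and pluripotency genes were again among those called in Tet2-/- cells at day 6. Grb10 was at 2.01 ± 0.016 RPKM against 156 ± 1.78 RPKM (log2 fold change −6.25 ± 0.15, edgeR adjusted p = 4.4e-11, n = 2), and Cpt1a, which encodes carnitine palmitoyltransferase of fatty acid oxidation, fell from 1.09 ± 0.253 to 0.205 ± 0.0298 RPKM (adjusted p = 9.1e-06). The imprinted zinc-finger gene Zim1 fell from 6.76 ± 3.91 to 0.330 ± 0.0544 RPKM and Peg3 rose from 105 ± 18.8 to 244 ± 60.3 RPKM. Pou5f1 fell from 12 ± 2.32 to 3.84 ± 0.288 RPKM (log2 fold change −1.59 ± 0.14, adjusted p = 4.5e-05) and Lefty1, a Nodal antagonist, from 3.53 ± 0.841 to 0.577 ± 0.287 RPKM. Of 24 naive genes 4 fell (7 adjusted over the list alone), with list adjusted p = 4.5e-04 and adjusted p = 0.60 with an estimated correlation. No other list was called. Of 18 Hox genes 2 fell (3 adjusted over the list alone), among them Hoxb5 at 4.28 ± 2.75 against 19.8 ± 5.28 RPKM (adjusted p = 0.041), a call lost without wild-type replicate 1 (0.17), wild-type replicate 2 (0.092) or Tet2-/- replicate 2 (0.18). Hoxb5, the other Hox gene called, Hoxb6, and Grb10 lie on chromosome 11, whose genes had a median change of −0.27 on the log2 scale, with 3 higher and 215 lower. Altogether 552 genes rose and 676 fell, or 310 and 965 by limma on log2(RPKM + 1). The total of 1,228 was 389 and 330 without wild-type replicates 1 and 2 and 380 without Tet2-/- replicate 2, and with only the 4 libraries compared in the fit it was 74, with Zim1, Peg3, Pou5f1 and Lefty1 not called.

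**Figure D3:**
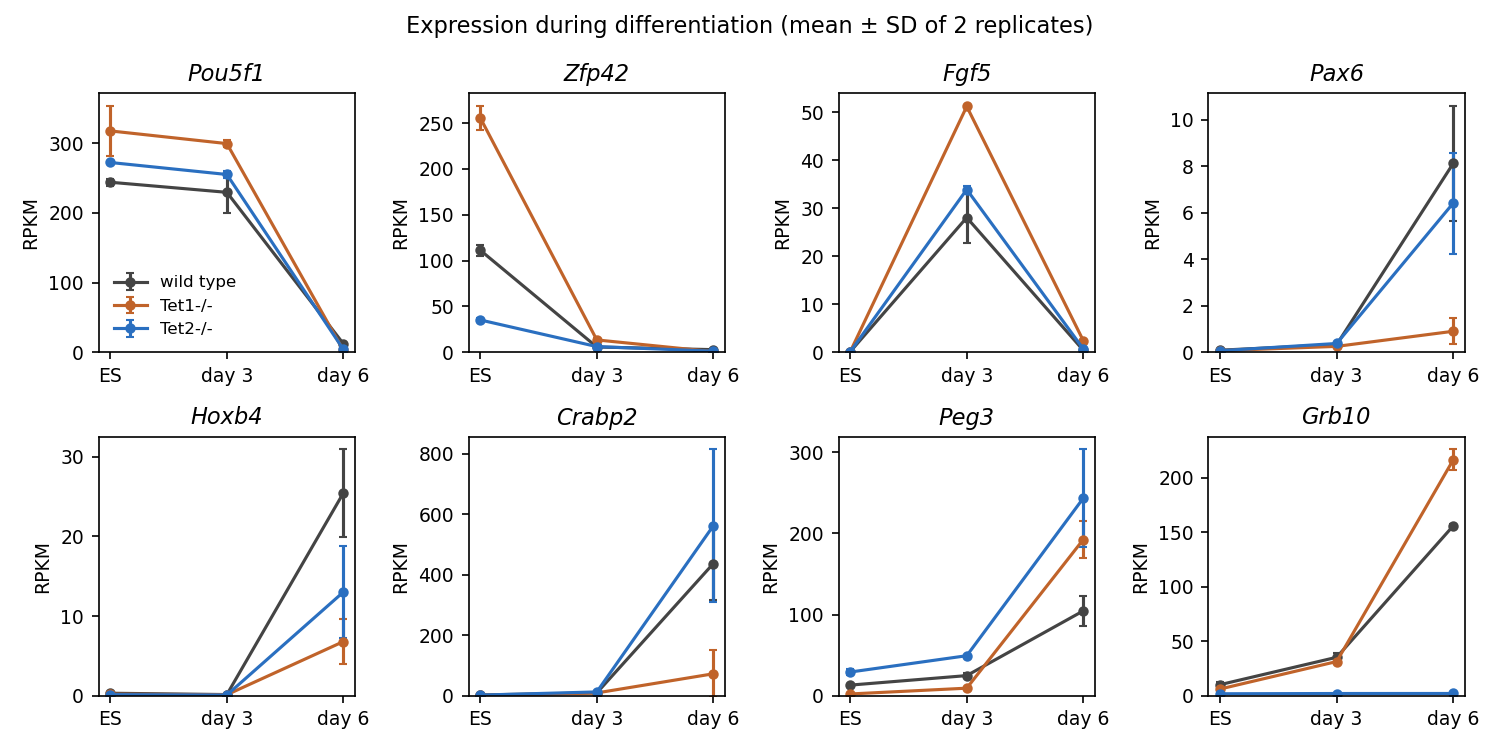
Expression in RPKM (vertical axes) of 8 genes in ES cells and at days 3 and 6 (horizontal axes) for wild type, Tet1-/- and Tet2-/-. Points show the mean of 2 replicates and error bars the SD. Grb10 climbed to 156 RPKM in wild type at day 6 and stayed at 2.01 RPKM in Tet2-/- cells, and Pax6 reached 8.12 RPKM in wild type and 0.899 RPKM in Tet1-/- cells.

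Whether the course from ES cells differed between genotypes was tested with interaction contrasts. In Tet2-/-, Esrp1, a splicing factor gene of epithelial cells, went from 0.223 to 23.0 RPKM by day 3 where wild type went from 1.74 to 28.0 RPKM (interaction log2 3.01 ± 0.51, edgeR adjusted p = 0.0075, n = 2). That call was lost with limma on log2(RPKM + 1), with adjusted p = 0.13, and with quantile normalization (0.12), and held without any single library. Grb10 went from 1.75 to 2.01 RPKM by day 6 in Tet2-/- and from 10.1 to 156 RPKM in wild type (−3.70 ± 0.18, adjusted p = 3.8e-07). In Tet1-/-, Nod1 went from 14.6 to 0.191 RPKM by day 6 and from 0.207 to 0.131 RPKM in wild type (−5.59 ± 0.62, adjusted p = 1.4e-04). Rbm24, a splicing regulator of muscle, went from 0.135 to 14.2 RPKM against 0.894 to 2.27 RPKM (6.06 ± 0.73, adjusted p = 2.5e-04). The interaction was called for 198 genes upward and 187 downward in Tet1-/- at day 3, 318 and 315 in Tet2-/- at day 3, 705 and 936 in Tet1-/- at day 6, and 973 and 943 in Tet2-/- at day 6. The last 3 became 190 and 405, 438 and 1,483, and 560 and 1,091 by limma on log2(RPKM + 1). In Tet1-/- the formative (5 higher of 14; 6 adjusted over the list alone), trophoblast (2 of 13; 5 adjusted over the list alone) and germline lists (1 of 5) were called up at day 3 with adjusted p = 5.2e-05, 6.3e-05 and 0.0048, and had adjusted p = 0.18, 0.18 and 0.56 with an estimated correlation. At day 6 in Tet1-/-, naive (0 higher and 12 lower of 24; 1 and 14 adjusted over the list alone), neuronal (0 and 5 of 13; 2 and 6) and germline lists (0 and 2 of 5; 0 and 4) were called down and the imprinted list (7 and 1 of 28; 9 and 1) up, with adjusted p = 4.3e-11, 7.2e-04, 0.0068 and 1.7e-04, and adjusted p = 0.06, 0.46, 0.52 and 0.29 with an estimated correlation. No list was called in Tet2-/- at either day.

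Many of these interaction counts moved with single libraries. For Tet1-/- at day 3 the total of 385 was 173 and 219 without Tet1-/- ES replicates 1 and 2, 228 and 176 without wild-type day 3 replicates 1 and 2, and 137 and 119 without Tet1-/- day 3 replicates 1 and 2. For Tet2-/- at day 3 the total of 633 was 262 and 1,407 without wild-type ES replicates 1 and 2, 283 without Tet2-/- ES replicate 2, 139 without wild-type day 3 replicate 2, and 184 and 106 without Tet2-/- day 3 replicates 1 and 2. For Tet1-/- at day 6 the total of 1,641 was 1,011 without wild-type day 6 replicate 1. For Tet2-/- at day 6 the total of 1,916 was 952 without wild-type ES replicate 1, 1,019 without Tet2-/- ES replicate 2, 999 and 1,049 without wild-type day 6 replicates 1 and 2, and 1,184 without Tet2-/- day 6 replicate 2.

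The title of the series speaks of the timing of reprogramming, so genes that change early in differentiation were followed in Tet2-/- cells. The lists came from Tet1-/- libraries, which do not enter the contrast of Tet2-/- with wild type, though they are part of the same fit. The 1,431 genes that had risen at least 2-fold by day 3 had a median difference of −0.040 on the log2 scale in Tet2-/- against wild type at day 3 (camera with a preset correlation, p = 0.10) and of 0.037 at day 6 (p = 0.87). The 1,460 genes that had fallen had median differences of 0.040 at day 3 and −0.037 at day 6 (p = 0.25 and 0.078 with the preset correlation). None of the 4 tests passed 0.05, and with an estimated correlation p was 0.22, 0.90, 0.65 and 0.49. All 4 medians lay outside those of 10,000 random lists of the same size matched on expression, a permutation p of 0.0002, the smallest these lists can give. Random lists treat genes as independent and ignore correlation between the genes of a list, so this p does not measure the spread between samples. In the reverse test, added after the data were examined, genes that had fallen by day 3 in Tet2-/- had a median difference of 0.090 in Tet1-/- against wild type at day 3, with 160 of 1,450 higher and 63 lower (p = 0.0029 with the preset correlation and 0.11 with an estimated one). The other 3 reverse tests had p = 0.069 (risen, day 3), 0.76 (risen, day 6) and 0.067 (fallen, day 6) with the preset correlation. With 0.1 in place of 1 added to the RPKM, camera with the preset correlation gave p = 0.048 for the reverse risen list at day 3 and p = 0.0044 for the reverse fallen list at day 3 (median 0.11). With the same 0.1, the fallen list from Tet1-/- was called up in Tet2-/- at day 3 by camera with the preset correlation (p = 0.032) while its median was −0.013. The other medians of the lists from Tet1-/- were then −0.089 (risen, day 3), −0.029 (risen, day 6) and −0.093 (fallen, day 6).

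Genes near windows with raised modification were compared with other genes that had tested windows. The genes within 10 kb of a window raised in Tet2-/- ES cells (6,516) had a median log2 difference of −0.037 in Tet2-/- ES cells, against 0.028 for the other 5,358 genes, with 17.6% and 11.9% of them lower (camera p = 0.10, and p = 0.019 with an estimated correlation). At day 3 and day 6 the p values were 0.56 and 0.66. Chromosome and gene length were not controlled for. Raised windows made up 2.92% of those tested on chromosome 11, 1.93% on chromosome 6 and 2.01% on chromosome 8. Median expression changes of these chromosomes in Tet2-/- ES cells were −0.16, −0.14 and 0.09. Within single loci, 24 of 96 windows at Dpys, 10 of 27 at Lefty2, 8 of 25 at Zfp42 and 5 of 13 at Ubd, a ubiquitin-like modifier gene, were raised in Tet2-/- ES cells, and all 4 genes were lower there. Grb10 had 2 raised and 31 lowered of 107 windows, and Rnase4 0 raised and 12 lowered of 34. These loci were chosen after their expression values were seen. Genes are not independent replicates, so these p values describe genes within these libraries.

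Finally, calls were compared across genotypes and days. In ES cells 440 genes were higher in both knockouts (138 for independent lists) and 533 lower in both (150), among them Olig1, Olig2 and Ubd. The fold changes of the 2 knockouts had a correlation of 0.475 across genes and a covariance of 0.167, where unchanged groups simulated against the same wild-type libraries gave 0.509 and 0.025, so the covariance exceeded the simulated one by 0.141. At day 3 the covariance was 0.072 against a simulated 0.024, and at day 6 it was 0.106 against 0.025. The correlation was 0.361 against a simulated 0.502 at day 3 and 0.353 against 0.510 at day 6. At every stage the correlation thus lay below the simulated one while the covariance lay above it. Simulated groups shared 0 calls in 10 simulations. Groups simulated without change give few calls, so this sets no expected number for the 440 and 533 shared genes. Part of the excess over independent lists may come from the shared controls. Without shared libraries, 111 genes were higher in Tet2-/- both in ES cells and at day 3 (25.8 for independent lists) and 158 were lower (38.2), among them Grb10 and Dpys. For Tet1-/- the ES and day 3 overlaps were 260 higher (51.4) and 274 lower (57.4), with Nod1 and Ipp, a kelch-repeat gene, among the former. ES and day 3 cells of a genotype may share a line, so differences between lines may add to these overlaps. In Tet2-/- chromosome 6 had 51 genes higher and 134 lower in ES cells, and 15 and 53 at day 3. Chromosome 11 had 46 and 274 in ES cells, and 4 and 32 at day 3.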

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

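The tests that weigh the day 6 pattern in Tet1-/- cells were chosen only after the result was seen, and the interaction contrasts were planned.

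Changes from ES cells that differed from wild type by the interaction test itself stood out for 385 genes in Tet1-/- and 633 genes in Tet2-/- at day 3, and for 1,641 genes in Tet1-/- and 1,916 genes in Tet2-/- at day 6. An interaction with ES cells as the start also holds the genes that differed in ES cells, such as Nod1 in Tet1-/-, whose levels approached wild type later. Uggt2, a glycoprotein-folding sensor gene, did so in Tet1-/-, going from 0.148 to 1.29 RPKM by day 3 while wild type went from 6.47 to 3.89 RPKM (interaction log2 4.41 ± 0.22, edgeR adjusted p = 3.5e-07). Grb10 and Zim1 in Tet2-/- moved further from wild type, Zim1 going from 0.295 to 0.330 RPKM by day 6 against 0.158 to 6.76 RPKM (−5.71 ± 0.65, adjusted p = 3.8e-04).

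In Tet1-/- cells at day 6, the neural progenitor list was lower than in wild type and single cardiac genes were higher, and the replicates differed widely, with Myl7 at 190 ± 216 RPKM. For the neural progenitor genes 1 library as the whole cause is argued against: without Tet1-/- replicate 1 their list, all 22 measured members, stayed lower (median −0.79 on the log2 scale, list adjusted p = 6.49e-05), with 8 members called lower and 1 higher. With an estimated correlation the list was not called, with adjusted p = 0.48 without replicate 1 and 0.31 with both libraries. The Tet1-/- group is then 1 library, and the spread comes from the other groups. Replicate 1 still carried more of the pattern, since 45.0% of all 2,219 genes called stayed past the threshold without it and 74.6% without replicate 2. The neural progenitor median was −1.42 without replicate 2. For the cardiac genes the same leave-out decides nothing, because their list was drawn up after their values were seen, and with only the 4 libraries compared in the fit Myl7, Nkx2-5 and Actc1 were not called. ES cells left in the cultures are also argued against, since naive pluripotency genes were lower in Tet1-/- (list adjusted p = 2.63e-12). A difference between single differentiation cultures stays open, because the labels name no batches and each group holds 2 samples.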

How the results depend on the processing

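The alternatives chosen only after the results were seen were DESeq2, edgeR with RLE scaling, limma on log2(RPKM + 1), the dispersion moderation first run, libraries less their median, and the added classes and lists.

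With 2 replicates per group, single libraries set many counts. Named genes kept direction and side of the threshold in 7,029 of 7,920 comparisons with an alternative, 875 lost their call, 16 gained one and none reversed. Named windows kept theirs in 370 of 505, 134 were lost and 1 reversed: the 5hmC window at Tlr2 stood at −0.34 points in Tet1-/- without Tet1-/- replicate 2 and reached 14.6 points without replicate 1. Gene list calls kept theirs in 651 cases, 42 were lost and 23 gained, and of 35 list calls 4 held with an estimated correlation. In the main tests of the 17 lists, median and test pointed opposite ways only for lists without a call, such as neuronal genes in Tet1-/- ES cells and imprinted genes in Tet2-/- at day 6. Among CpG classes 59 stayed and 2 reversed: classed on wild-type replicate 2, windows at 10 to 50% differed by 9.03 points in Tet2-/- and those under 10% by 0.27 points in Tet1-/-. The window counts moved with read minimums, window size and the libraries used. Depth limits which windows can be tested: at day 3 these were 834,274 with at least 20 reads, 1,415,591 with at least 10 and 124,222 with at least 50. The labels do not say that a replicate number marks a shared batch, and with 2 libraries per group the values do not settle whether numbers pair the samples. Deviations of same-numbered RNA libraries correlated between −0.44 and 0.70 over 36 pairs of groups, over 0.1 in 6 and under −0.1 in 7. The ES groups had positive correlations with each other (0.33, 0.29 and 0.17), as did wild type and Tet2-/- at day 6 (0.70), and in TAB-Seq of ES cells chromosome X reads per 1000 autosomal ones were 14.6, 14.8 and 16.2 in replicates 1 and 18.1, 19.1 and 18.8 in replicates 2 of wild type, Tet1-/- and Tet2-/-, so a shared batch of ES replicates stays open. With the replicate number as a block the gene counts were 1,965 in Tet1-/- and 3,393 in Tet2-/- ES cells, 1,252 and 418 at day 3 and 2,107 and 1,120 at day 6, all within 1.5 times those without it. Where a cause is not given, the cause was not tested.

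With only the groups compared in the fit, which leaves 2 residual degrees of freedom, the counts were 935 (Tet1-/- ES), 1,464 (Tet2-/- ES), 2,466 (Tet1-/- day 3), 1,049 (Tet2-/- day 3), 568 (Tet1-/- day 6), 74 (Tet2-/- day 6) and 5,466 (Tet2-/- against Tet1-/- at day 3). DESeq2 called 836 genes in Tet2-/- at day 3 and 736 and 1,259 interactions at day 3 in Tet1-/- and Tet2-/-. Leaving out each library in turn gave 1,169 to 1,852 (Tet1-/- ES), 1,904 to 3,515 (Tet2-/- ES), 298 to 676 (Tet1-/- day 3), 85 to 381 (Tet2-/- day 3), 1,026 to 2,179 (Tet1-/- day 6), 330 to 1,009 (Tet2-/- day 6), 6,015 to 6,634 (wild type, day 3), 7,237 to 7,693 (wild type, day 6), 1,147 to 2,316 and 337 to 653 (Tet2-/- against Tet1-/-, ES and day 3), and interactions of 119 to 394, 106 to 1,407, 1,011 to 1,762 and 952 to 2,624 in the order given before.

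Windows of combined modification in Tet1-/- ES cells numbered 121,345 with at least 50 reads, 140,082 at 500 bp, 384,757 with technical replicate 1 alone, 166,575 by limma and 88,735 by limma with a replicate block, 5,443 less library medians and 13,273 to 661,890 with a library left out. In Tet2-/- ES cells they numbered 177,169 with at least 50 reads, 226,788 at 500 bp, 383,496 by limma and 262,034 by limma with a replicate block, 72,311 less library medians and 6,096 to 679,381 with a library left out. Windows of 5hmC in Tet1-/- numbered 13,495 with at least 50 reads, 1,658 at 500 bp, 313 with technical replicate 1 alone, 0 by limma, with or without a block, less library medians and with the moderation first run, against 305,398 at an unadjusted p under 0.05 by the quasi-binomial test, and 1 to 44,672 with a library left out. In Tet2-/- 5hmC gave 0 less library medians and 109,354 to 308,184 with a library left out. Day 3 gave 521 with at least 50 reads, 621 at 500 bp, 1 by limma, 165 with a block, 1 less library medians and 1,001 to 1,299 with a library left out.

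Global differences with a library left out were −15.4 to −6.35 (Tet1-/-) and −13.2 to −4.15 points (Tet2-/-) for combined modification, −2.18 to −0.99 and −3.18 to −1.99 for 5hmC, and −1.25 to −0.24 at day 3. Genes near raised windows had p = 0.0192 with an estimated correlation and p = 0.0272 with no flank. Against matched random lists, which treat genes as independent, the course of genes changed by day 3 had permutation p = 0.0002 for each of the 4 tests. This is the smallest 10,000 lists give. With 0.1 added, camera with the preset correlation gave p = 0.0324 for the fallen list at day 3.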

Other observations

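The tests of genes near windows raised in Tet1-/- ES cells or in Tet2-/- at day 3, of 5hmC loss and of chromosomes were chosen only after the results were seen. The gene comparisons and the permutation test of global levels were planned.

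Further single genes passed the test at day 6 in Tet1-/- cells. Fn1, which encodes fibronectin, rose from 66.6 ± 17.3 to 163 ± 7.32 RPKM (log2 fold change 1.40 ± 0.23, edgeR adjusted p = 0.0013, n = 2), and Fgf5 stood at 2.40 ± 0.0942 against 0.392 ± 0.0718 RPKM (log2 fold change 2.90 ± 0.29, adjusted p = 4.3e-05). Cyp26a1, an enzyme that degrades retinoic acid, rose from 10.4 ± 0.886 to 36.3 ± 0.207 RPKM, and Lhx1 rose from 1.88 to 5.68 ± 1.60 RPKM. Ddx4, a germ-cell RNA helicase gene, fell from 1.51 to 0.155 RPKM (log2 fold change −3.67 ± 0.31).

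The 922 genes within 10 kb of a window raised in Tet1-/- ES cells had a median log2 difference of −0.175 in Tet1-/- ES cells against 0.0087 for the others, with 25.6% and 6.92% of them lower (camera p = 5.9e-09, and p = 1.4e-05 with an estimated correlation). At day 3 the p was 0.026 and at day 6 it was 0.30. Chromosome and gene length were not controlled for. Windows raised in Tet1-/- made up 0.363% of those tested on chromosome 6, 0.105% on chromosome 8, 0.228% on chromosome 11 and 0.351% on chromosome 17. Median expression changes of these chromosomes in Tet1-/- ES cells were −0.13, 0.13, −0.16 and 0.018. Near windows raised in Tet2-/- at day 3, 494 genes had p = 0.043 in ES cells and p = 0.025 at day 3 with the preset correlation, where 6.07% were lower against 1.95% of the others. Whether the relation differed between the knockouts was not tested.

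Combined modification over the genome stood lower in both knockouts. Loss of 5hmC, which methylC-Seq reads as modified, is argued against as the whole cause: in windows with 2 to 5% 5hmC in wild type, the lowest wild-type replicate lay 8.01 points above the highest Tet2-/- replicate, where at most 3.71 points of 5hmC were there to lose. For Tet1-/- the same gap was 4.09 points against at most 2.95 points of 5hmC, which argues against it there too, with TAB-Seq levels taken as called. Over the genome the gap was 4.04 points in Tet1-/- against a largest 5hmC difference between replicates of 2.22 points, and 3.61 against 3.29 points in Tet2-/-, a small margin. Differences between cultures or libraries stay open too, since the wild-type replicates lay 9.04 points apart and 2 against 2 cannot give an exact permutation p under 0.333. By day 3 the difference in Tet2-/- was −0.75 points.

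Genes of chromosomes 8 and 11 shifted as a whole in ES cells of both knockouts, with median expression changes in Tet1-/- and Tet2-/- of 0.13 and 0.09 on chromosome 8 and of −0.16 and −0.16 on chromosome 11 on the log2 scale. They were not alone: chromosome 6 had medians of −0.13 and −0.14, and in Tet2-/- at day 3 a median of −0.16 (15 higher, 53 lower) with 55.3 and 55.8 DNA reads per 1000 against 61.0 and 62.0 in wild type. Over the 19 autosomes, the DNA read share and the median expression change rose together in Tet1-/- (Pearson r = 0.864, Spearman rho = 0.919, each with permutation p = 1.0e-05, the smallest the permutations can give), also without chromosomes 11 and 8 (r = 0.670, permutation p = 0.0029). Different libraries gave both measures, which argues against coverage bias of the DNA libraries alone and is consistent with another copy number of chromosomes 8 and 11 in part of the cells. Not every chromosome followed: in Tet1-/- chromosome 6 had a median of −0.13 with a DNA share change of −0.031 on the log2 scale, and chromosome 4 a median of −0.0088 with a share change of −0.069. In Tet2-/- r was 0.689 (permutation p = 8.5e-04; rho = 0.639, p = 0.0040), and without chromosomes 11 and 8 it was 0.447 (permutation p = 0.068). At day 3, with other DNA and RNA libraries, r in Tet2-/- was 0.768 (permutation p = 1.7e-04; rho = 0.581, p = 0.011) and 0.623 without chromosomes 8 and 11 (permutation p = 0.0032). There chromosome 8 had 63.2 and 63.1 reads per 1000 in the Tet2-/- replicates against 52.5 and 53.3 in wild type, and chromosome 11 had 65.8 and 64.7 against 74.1 and 70.9, with median expression changes of 0.12 and −0.17. This argues against coverage bias alone in Tet2-/- too and is consistent with another copy number at day 3, while for Tet2-/- ES cells copy number stays open. In Tet2-/- ES cells chromosome 13 had a median of −0.13 with a share change of −0.028, and chromosomes 3 and 15 had share changes of 0.096 and 0.093 with medians of 0.0050 and 0.034. At day 3 chromosome 13 had a share change of −0.10 with a median of 0.021. In Tet1-/- the median expression changes of chromosomes 8 and 11 were 0.075 and −0.010 at day 3 and 0.0065 and −0.054 at day 6. The shifts of Tet1-/- ES cells thus did not keep their size, and a copy number fixed in that line is not shown. The wild-type libraries are common to both ES comparisons, so the wild-type line may be the one that differs in ES cells.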
